A study of Mus musculus with 18 samples.

How the data were processed

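RNA-seq of 18 pDC libraries was analysed. The deposited values are raw counts per gene, whole numbers made by the authors, and were used as supplied for 54532 genes. The submitters' notes name STAR as the aligner and mm10 as the genome. The aligner version, the counting program, the strand setting, the handling of reads with several matches and the annotation release were not given in the sources used here. Genes are called by the symbols of the count table, and 100 symbols are shared by more than 1 identifier. Of the versioned Ensembl identifiers, 97.8% were found in GENCODE M21 (GRCm38, the Ensembl name for mm10), and coordinates are from that release. Reads were not realigned.

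Groups, comparisons, gene lists, thresholds and alternatives were fixed before the data were examined. The 6 groups of 3 libraries were fitted together in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood negative binomial model. Genes were kept by filterByExpr on the groups with its minimum count of 10, library sizes were taken over the kept genes, and libraries were scaled by TMM. Dispersions were estimated with the robust option. The common dispersion was 0.000951, a biological coefficient of variation of 3.08%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and every adjusted p for a gene is from edgeR unless another tool is named. The standard error (SE) given with a gene's log2 fold change is its absolute value divided by the square root of the F statistic. For large changes from few counts this value is too small and should not be read as the precision of the change. Means and SDs are over 3 libraries in TMM-scaled CPM.

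The comparisons were imiquimod with the vehicle of the same time at 6 h and at 16 h, the difference between those effects (16 h minus 6 h), the vehicle at 0 h with untreated cells, and the vehicle at 6 h and at 16 h with the vehicle at 0 h. Imiquimod was also compared with the vehicle at 0 h for the lists, a comparison added after the data were seen.

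Named genes follow a rule. The 8 highest and 8 lowest log2 fold changes were taken for each imiquimod comparison, 6 each way for the difference between the effects and 5 each way for the others. Such genes had to be called and have a mean of at least 10 CPM over the libraries compared. Except for the difference between the effects, all 3 libraries of one group also had to lie on the same side of all 3 of the other. Gene models, clones, pseudogenes, small RNAs, rRNAs and mitochondrial genes were left out. A panel of 22 genes was fixed beforehand. A gene that the rule picks at 6 h is not reported here. In the lists, some of the 4 called members with the largest absolute change are given. Not all 4 are always named, and some lists have 1 or none named, so members with larger changes can go unnamed. Members outside this rule, named because a count held 5 or fewer, were chosen after their values were seen. Where a group had 0 counts over its 3 libraries, the fold is given as at least the ratio to a floor of 3 counts, or as a multiple of that floor. The counting error of the other group is left out, so such a bound is too high where its counts are few. With 1 to 3 counts the ratio of counts is given with its exact 95% interval.

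Of 26 lists, 24 had at least 4 tested members. They were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The lists were interferon-stimulated genes, inflammatory cytokines and chemokines, NF-kappaB target and feedback genes, death ligands and cytotoxic effectors, maturation and co-stimulation, immune checkpoint and regulatory genes, MHC class II presentation, MHC class I presentation, the Toll-like receptor pathway, pDC identity, cDC1 markers, cDC2 markers, monocyte and macrophage markers, neutrophil and basophil or mast cell markers, B cell markers, T and NK cell markers, cell cycle, apoptosis regulators and caspases, p53 targets, the unfolded protein and integrated stress response, glycolysis and hypoxia response, cholesterol synthesis, immediate-early genes and mitochondrially encoded mRNAs. Type I and III interferon genes had 0 tested members and erythroid markers 1. Those 2 lists were not tested.

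The alternatives were DESeq2 size factors, no expression filter, a filter of 1 CPM in 3 libraries, a replicate block, a fit of only the groups compared, DESeq2 1.42.0 (Wald test), each library left out in turn, camera with an estimated correlation, and fry. Scaling by library totals and the list comparison with the vehicle at 0 h were chosen after the data were seen. So was leaving out rRNA genes, mitochondrial rRNA genes and 3 rRNA-like genes (Gm26917, Gm42418 and Gm23935), which left 14858 genes tested.

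The fit was tested on simulated data with known changes for 14876 genes. Only 200 genes and a planted list were changed, in the imiquimod libraries at 6 h alone, and all other means were equal. In the data 76.9% of genes were called at 6 h, so false calls under changes on that scale were not tested. In the 6 h comparison it found 62%, 84%, 98% and 100% of 50 genes changed 1.25-, 1.5-, 2- and 4-fold, and 9 of 204 calls were false (4.41%). In the difference between the effects it found 44%, 68%, 94% and 100%, and 13 of 184 calls were false (7.07%). In 4 comparisons with no planted change there were 0 calls. A list planted at 1.5-fold was called (camera adjusted p = 2.33e-55), and 0 of 25 unchanged lists were.

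Other software was Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.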

Results

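Plasmacytoid dendritic cells (pDCs), the blood and tissue cells known for secreting type I interferon, were grown from bone marrow of wild-type C57BL/6 mice in 80 ng/mL Flt3 ligand for 7 days. They were enriched on beads through the surface protein B220, to a routine purity of 80%. Wells of a 96-well plate were then given imiquimod, an agonist of the RNA-sensing receptor TLR7, at 2.5 µg/mL, or the vehicle, which the series names LAL (Limulus amebocyte lysate). The labels do not say whether this was the lysate itself or LAL reagent water. RNA was collected at 0, 6 and 16 h. The series concerns the tumor-killing capacity of pDCs activated in this way. Total RNA depleted of rRNA was sequenced as directional paired-end libraries of 75 nt per read on a NextSeq500. There were 6 groups of 3 libraries: untreated cells at 0 h, vehicle at 0, 6 and 16 h, and imiquimod at 6 and 16 h.

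Total counts per library ran from 10609741 to 13447018, a ratio of highest to lowest of 1.27. Of 54532 genes, 28361 had at least 1 count and 14876 passed the expression filter. The first principal component held 83.1% of the variance of the 2000 most variable genes and the next held 7.9%. p-values measure only the spread between these libraries, which may be technical, since the labels do not say whether the libraries of a group came from separate cultures or animals. Counting intervals cover counting error only, and floors cover that of the group with 0 counts alone. Comparisons, thresholds and gene lists were set before the data were examined. Fold changes are log2 values with n = 3 libraries per group, and CPM values are means with SD. The standard error (SE) beside a fold change is derived from its test statistic and is too small for large changes from few counts. Ighg2c, for example, had an SE of 0.25 at 6 h and 0.12 at 16 h, but 0.96 for the difference between those effects.

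The first comparison asked which genes differed between imiquimod and vehicle at 6 h. Cxcl10 (ENSMUSG00000034855.13, mm10 chromosome 5, 92346638 to 92348889), which encodes a chemokine that attracts T cells, rose from 0.134 ± 0.125 to 244 ± 7.89 CPM. Its log2 fold change was 10.75 (SE 0.13, edgeR adjusted p = 4.37e-70). Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981), the gene of the inflammatory cytokine interleukin 6, rose to 153 ± 6.92 CPM, with a log2 fold change of 10.08 (SE 0.14, adjusted p = 3.63e-70). Cxcl9, a related T cell chemokine gene, rose by 10.11 (SE 0.15), and Ccl3, a chemokine gene for monocytes and T cells, by 9.52 (SE 0.098). Slfn4 (ENSMUSG00000000204.16, chromosome 11, 83175186 to 83190216), an interferon-induced Schlafen family gene, had 1257 counts over the imiquimod libraries and 0 in the vehicle, a rise of at least 518-fold. Slfn1 of the same family rose at least 450-fold and Wfdc21, a gene of a small secreted protease-inhibitor-like protein, at least 418-fold. Npr1, the gene of a natriuretic peptide receptor, had 1377 counts against 2, a ratio of 852 (exact 95% interval 235 to 7040).

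The largest falls at 6 h included Hpgd (chromosome 8, 56294585 to 56321043), which encodes the enzyme that inactivates prostaglandins. It had 1 count with imiquimod and 844 with vehicle, a ratio of 682 (exact 95% interval 122 to 27000). Tet1, a DNA demethylase gene, fell from 40.4 to 0.781 CPM, a log2 fold change of -5.67 (SE 0.16, adjusted p = 2.14e-48). Cxcr3, the receptor gene for the products of Cxcl9 and Cxcl10, fell by 5.03 (log2 -5.03, SE 0.17, adjusted p = 1.6e-41). Cd209a, a C-type lectin gene of dendritic cells, changed by -5.44 (SE 0.19) and Hepacam2, a cell adhesion gene, by -6.03 (SE 0.19). Tm6sf1, a lysosomal membrane protein gene, changed by -5.12 (SE 0.09) and Tenm4, a teneurin gene, by -4.82 (SE 0.16). In all, 5602 genes were higher and 5837 lower, 76.9% of those tested, and 35.5% changed at least 2-fold. Scaled by library totals, a choice made after seeing the data, 3704 were higher and 8222 lower, a median shift of -0.35, so that 31.1% of calls were higher in place of 49%.

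Interferon-stimulated genes rose at 6 h in all 61 measured members (median 4.59, camera adjusted p = 1.31e-132), with 61 higher when adjusted over the list alone. Rsad2, which encodes the antiviral enzyme viperin, rose by 8.94 (SE 0.082), Oasl1, a gene of the 2'-5'-oligoadenylate synthetase family, by 8.77 (SE 0.088) and Isg15, a ubiquitin-like modifier gene, by 8.40 (SE 0.082) from 1.48 to 500 CPM. Ifit3b changed by 8.61, but its reads are uncertain in their division from those of Ifit3. Irf7, the transcription factor gene that drives interferon production, rose by 5.03 (SE 0.094), from 39.1 to 1270 CPM. Bst2, a surface antigen of pDCs, rose by 0.87 (SE 0.045).

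Type I and III interferon genes themselves had few counts. Over the 20 listed type I and III interferon genes there were 49 counts in the 3 imiquimod libraries at 6 h, or 1.32 CPM, against 3 in the vehicle. At 16 h there were 18, or 0.462 CPM, against 1. Ifnb1 had 13 counts at 6 h and 4 at 16 h and none in any vehicle or untreated library. Scaled for depth, its counts at 6 h were 5.36 times the floor (edgeR adjusted p = 0.000369 with no expression filter). At 16 h they were 1.14 times the floor and no rise was called (edgeR adjusted p = 0.114 with no filter). Ifnl2, an interferon lambda gene, had 10 counts at 6 h and 7 at 16 h with imiquimod. The Ifna genes together had 23 and 6 counts, of which Ifna4 had 1 and 0. A median of 12.9% of the 75 nt windows of 13 Ifna genes was shared with another gene's transcripts, which leaves the division of such reads uncertain, but 0% for Ifna4. Ifng, the type II interferon gene, chosen after its values were seen, had 43 counts against 1 at 6 h (edgeR adjusted p = 3.77e-10) and 195 against 0 at 16 h (adjusted p = 8.27e-22), or 1.4 and 4.95 CPM with imiquimod.

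**Figure D1:**
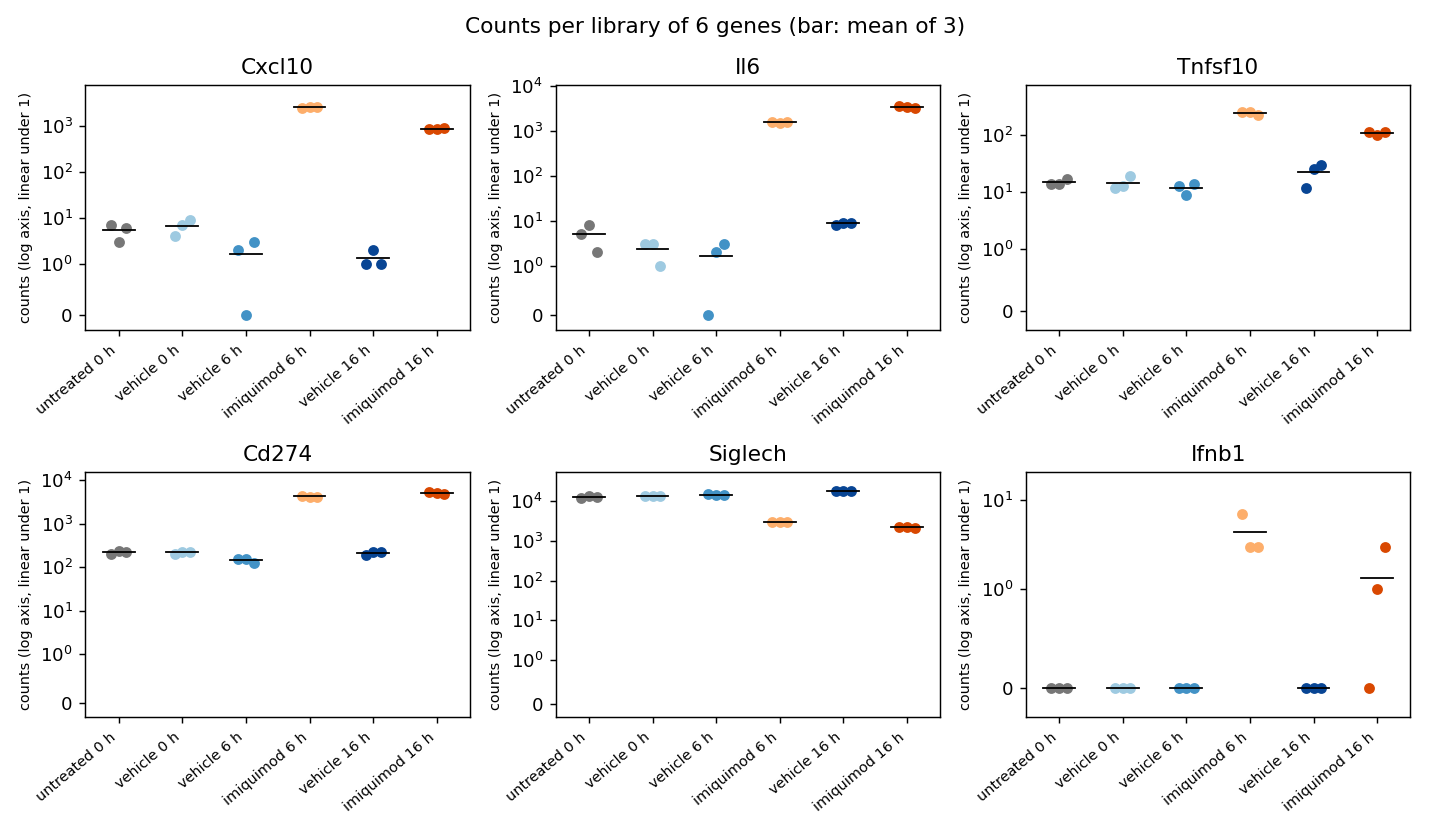
Raw counts per library of Cxcl10, Il6, Tnfsf10, Cd274, Siglech and Ifnb1 in the 6 groups, on a log axis that is linear under 1; points are libraries and bars the mean of 3. Ifnb1 had counts in the imiquimod groups alone, 13 at 6 h and 4 at 16 h over 3 libraries.

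Inflammatory cytokine and chemokine genes rose in 23 of 25 measured members at 6 h (median 6.39, or 6.26 with members absent from the vehicle set at their bounds; adjusted p = 2.48e-34), with Il12a lower (-0.89) and Il18 not called (0.08). Cxcl11, another ligand gene of CXCR3, rose at least 134-fold. Il12b, which encodes the p40 chain of interleukin 12, rose from 2.33 ± 0.739 to 900 ± 7.71 CPM, by 8.58 (SE 0.066, adjusted p = 6.96e-87). Tnf rose from 3.82 ± 0.328 to 294 ± 21.9 CPM, by 6.26 (SE 0.078), and Ccl5, a T cell chemokine gene, by 6.17 (SE 0.076). NF-kappaB target and feedback genes rose in 29 of 30 members (median 2.75, adjusted p = 1.15e-57), and Sod2 was not called (0.01). Among them Ptgs2, the inducible cyclooxygenase gene, rose by 7.08 (SE 0.23). Bcl2a1a and Bcl2a1d, genes of survival proteins, changed by 5.86 and 5.19, with reads that are uncertain in their division within the Bcl2a1 family. These counts were the same when adjusted over the list alone.

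Death ligand and cytotoxic effector genes, the list closest to the killing of tumor cells, held 13 measured members. At 6 h 8 were higher, 3 lower and 2 not called (median 0.82, adjusted p = 0.00194), the same when adjusted over the list alone. Tnfsf10 (chromosome 3, 27317028 to 27342427), which encodes the death ligand TRAIL, rose from 0.951 ± 0.233 to 24.2 ± 1.67 CPM, by 4.66 (SE 0.17, adjusted p = 2.47e-39). Lta, the lymphotoxin alpha gene, had 1837 counts against 3, a ratio of 758 (exact 95% interval 259 to 3680). Nos2, the inducible nitric oxide synthase gene, had 172 against 2, a ratio of 106 (29 to 886). The lower members were Klrd1 (-2.38), Ltb (-1.16) and Gzmm (-0.85), while Tnfsf14 and Ctsw were not called. Gzmb, which encodes granzyme B, was under the filter with 34 counts against 0, at least 14-fold (adjusted p = 1.49e-09 with no filter). For Fasl (4 counts against 1) and the perforin gene Prf1 (1 against 1) no difference was detectable at this depth.

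Maturation and co-stimulation genes rose in 21 of 22 members at 6 h (median 3.52, adjusted p = 1.39e-38), and Cd48 was lower (-0.71). Cd40, whose product receives T cell help, rose by 5.48 (SE 0.049) from 15.1 to 676 CPM, and Ccr7, the lymph node homing receptor gene, by 4.80 (SE 0.042) from 48.7 to 1350 CPM. Cd80 and Cd86, the co-stimulatory ligand genes for CD28, rose by 3.52 (SE 0.064) and 3.51 (SE 0.049). Checkpoint and regulatory genes were higher in 13 of 18 members and lower in 5 (median 3.44, adjusted p = 1.2e-05). Cd274 (chromosome 19, 29367455 to 29388095), which encodes PD-L1, rose by 5.17 (SE 0.053) from 11.6 to 417 CPM. Il10, the gene of an anti-inflammatory cytokine, had 192 counts against 1, a ratio of 238 (exact 95% interval 42.1 to 9430), and Socs3, a cytokine signalling inhibitor gene, rose by 5.75 (SE 0.068). The lower members were Vsir (-2.05), Entpd1 (-1.45), Havcr2 (-1.12), Tgfb1 (-0.43) and Tnfrsf14 (-0.26). Counts for both lists were the same when adjusted over the list alone.

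MHC class I presentation genes rose in all 23 members at 6 h (median 1.83, adjusted p = 4.13e-24). Nlrc5, the class I transactivator gene, rose by 3.22 (SE 0.037) and Psme2, an immunoproteasome activator gene, by 2.52 (SE 0.051). H2-Q7 and H2-Q4 changed by 3.08 and 2.88, with reads uncertain in their division among class I genes. Of 14 MHC class II genes, 10 were higher and 4 lower (median 0.79, adjusted p = 0.0142), a call lost at adjusted p = 0.402 with an estimated correlation and at 0.0574 under scaling by library totals. Ciita, the class II transactivator gene, rose by 2.32 (SE 0.033) and Cd74, the invariant chain gene, by 1.48 (SE 0.041). March1, whose product removes class II from the surface, fell (-2.05, SE 0.052), and H2-Ob (-0.59), H2-Oa (-0.36) and H2-DMa (-0.27) were lower. These counts were the same when adjusted over the list alone.

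Cholesterol synthesis genes rose in all 20 members at 6 h (median 1.86, adjusted p = 5.57e-24). Idi1, the isopentenyl diphosphate isomerase gene, rose by 3.20 (SE 0.05), and Hmgcs1, the HMG-CoA synthase gene, by 2.71 (SE 0.034). Unfolded protein and integrated stress response genes rose in 21 of 22 members (median 1.59, adjusted p = 7.38e-10), among them Chac1, a glutathione-degrading enzyme gene (3.60, SE 0.24), and Asns, the asparagine synthetase gene (3.03, SE 0.16); Xbp1 was lower (-0.25). Immediate-early genes were higher in 15 of 24 members and lower in 6 (median 1.79, adjusted p = 3.84e-09). The heat shock genes Hspa1a and Hspa1b rose by 4.87 (SE 0.11) and 4.79 (SE 0.082), and Myc by 4.31 (SE 0.084). How far Hspa1a and Hspa1b share reads was not tested. Apoptosis regulators were higher in 20 of 29 members and lower in 6 (median 0.45, adjusted p = 0.00018), including Bcl2l1, which encodes the survival protein BCL-XL (5.15, SE 0.06), Casp4, an inflammatory caspase gene (4.56, SE 0.088), and Fas, a death receptor gene (4.05, SE 0.15). All these counts were the same when adjusted over the list alone. Immediate-early genes also fell in the vehicle from 0 to 6 h (median -1). Against the vehicle at 0 h, a list comparison added after the data were seen, their median in imiquimod at 6 h was 0.36 (camera adjusted p = 0.0397, or 0.428 with an estimated correlation).

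Among lineage lists at 6 h, cDC1 markers were lower in 12 of 13 members (median -1.76, adjusted p = 7.61e-05). Sept3, a septin gene, fell (-4.67, SE 0.098), as did Naaa, a lysosomal amidase gene (-2.74, SE 0.059), while Cd36, a scavenger receptor gene, rose by 3.40 (SE 0.066). pDC identity genes were higher in 10 of 23 members and lower in 13 (median -0.32, adjusted p = 0.209). Siglech (ENSMUSG00000051504.18, chromosome 7, 55768178 to 55778925), a lectin gene used to mark mouse pDCs, fell from 1150 ± 17.4 to 299 ± 0.783 CPM (-1.95, SE 0.032, adjusted p = 3.12e-64). Upb1, a pyrimidine catabolism gene, fell (-2.61, SE 0.099), as did Ccr9, a gut-homing receptor gene (-2.53, SE 0.04). Tcf4, the transcription factor gene that maintains pDCs, rose by 0.30 (SE 0.034), but changed by -0.05 under scaling by library totals. Toll-like receptor pathway genes were higher in 15 of 27 members and lower in 8 (median 0.44, adjusted p = 0.04), a call lost at 0.102 under scaling by library totals. Tlr7 (chromosome X, 167304929 to 167330558), the receptor gene for imiquimod, rose by 1.18 (SE 0.054) from 181 to 408 CPM, Tlr4 changed by -2.91 (SE 0.23) and Tlr3 by -2.07 (SE 0.14).

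The remaining lists were not called at 6 h. Adjusted p was 0.068 for glycolysis and hypoxia response, 0.0823 for monocyte and macrophage markers, 0.764 for B cell markers, 0.814 for p53 targets, 0.874 for cDC2 markers, 0.884 for neutrophil and basophil or mast cell markers, 0.958 for cell cycle, 0.991 for mitochondrially encoded mRNAs and 0.996 for T and NK cell markers. Glycolysis genes were higher in 14 of 22 members and lower in 5, and p53 targets higher in 10 of 20 and lower in 8, with Cdkn1a, a cell cycle inhibitor gene, up 3.65 (SE 0.053). B cell markers were higher in 3 of 11 and lower in 8, monocyte markers higher in 7 of 13 and lower in 6, and cDC2 markers higher in 4 of 11 and lower in 5. Cell cycle genes were higher in 15 of 34 members and lower in 14. Of 4 neutrophil and mast cell markers Csf3r was higher and Prtn3 lower, of 6 T and NK cell markers Gata3 and Klrb1c were higher, and of 7 mitochondrial mRNAs mt-Co1 was higher. Of these, Csf3r was not called without imiquimod 6 h replicate 1 (0.71), Klrb1c without vehicle 6 h replicate 1 (1.51) or imiquimod 6 h replicate 2 (1.77), and mt-Co1 without imiquimod 6 h replicate 3 (0.35). mt-Co1 stood at 0.22 without vehicle 6 h replicate 2, and was not called in a fit of only the groups compared (0.39) or, like Csf3r (0.58), under scaling by library totals (0.04). Counts adjusted over the list alone differed for the mitochondrial list, with 0 called. The median, mean and test differed in sign for cDC2 markers (-0.24, -0.69, up), monocyte markers (0.38, 0.29, down), neutrophil markers (0.47, -0.06, down), cell cycle (-0.03, 0.1, down) and mitochondrial mRNAs (0.12, 0.14, down). Ermap, the 1 erythroid marker tested, was lower. Of 14 lists called at 6 h, 13 held with an estimated correlation.

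**Figure D2:**
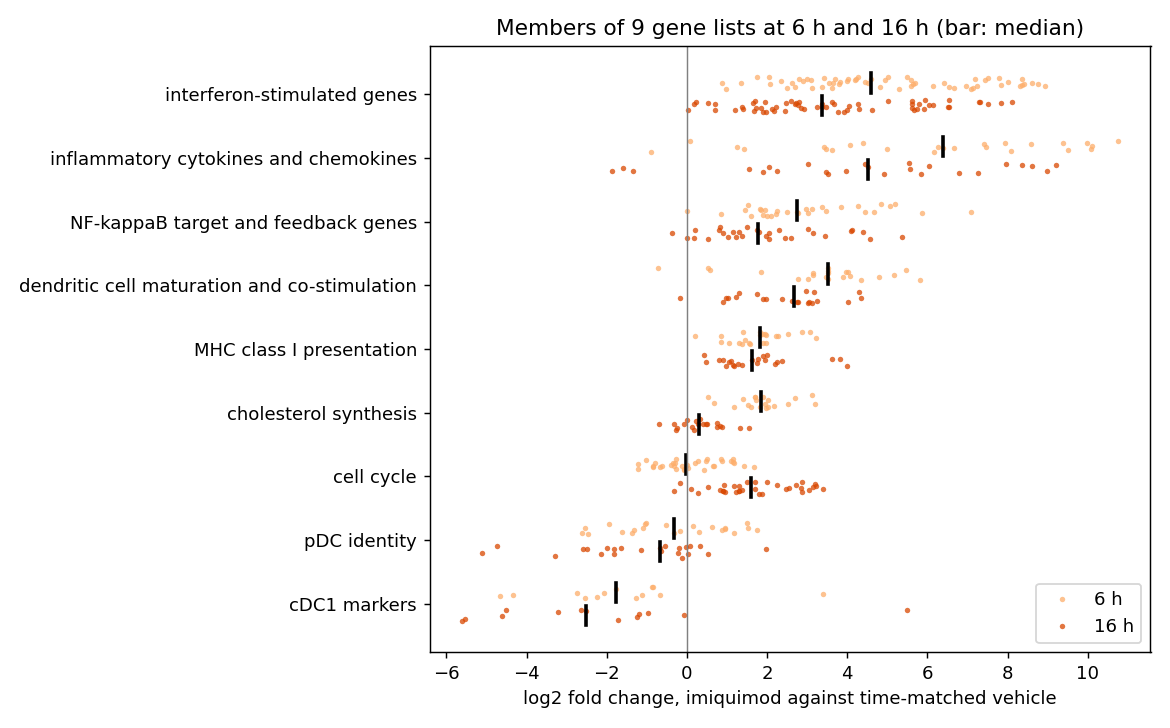
Log2 fold change of each measured member of 9 gene lists, imiquimod against vehicle at 6 h (light) and 16 h (dark); points are genes and the black bar is the median. Medians ran from 6.39 for cytokines at 6 h to -2.51 for cDC1 markers at 16 h.

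At 16 h the same question was asked against the vehicle at 16 h. Il6 rose from 0.772 to 256 ± 4.13 CPM, by 8.35 (SE 0.099, edgeR adjusted p = 1.48e-73), and Cxcl10 from 0.119 to 65.7 ± 6.06 CPM, by 8.99 (SE 0.18, adjusted p = 1.71e-55). Ighg2c, the constant region gene of the antibody class IgG2c, rose from 0.296 to 279 ± 9.87 CPM, by 9.83 (SE 0.12, adjusted p = 9.01e-65). Wfdc21 had 3049 counts against 0, at least 867-fold, and Gpr31b, a G protein-coupled receptor gene, 1207 against 0, at least 343-fold. Tnfsf15, a TNF family ligand gene, rose by 8.27 (SE 0.15) and Cd300e, a myeloid activating receptor gene, by 8.19 (SE 0.23). Lta had a ratio of counts of 439 (exact 95% interval 150 to 2130).

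Hpgd fell at least 303-fold at 16 h and Cd209a at least 295-fold, each with 0 counts in the imiquimod libraries. Matn2, a matrix protein gene, had 1 count against 722, a ratio of 847 (exact 95% interval 152 to 33500). Hrh1, a histamine receptor gene, fell (-7.69, SE 0.21, adjusted p = 6.46e-49), as did Abca6, a lipid transporter gene (-6.80, SE 0.21), Hepacam2 (-6.74, SE 0.21), Plekha6, a gene of a pleckstrin-domain protein (-6.44, SE 0.16), and B3galt5, a glycosyltransferase gene (-6.08, SE 0.18). There were 5818 genes higher and 5672 lower, 77.2% of those tested.

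At 16 h interferon-stimulated genes were higher in 60 of 61 members (median 3.36, adjusted p = 4.84e-68), with Oasl1 at 8.10 (SE 0.11), Isg15 at 7.52 (SE 0.098) and Bst2 not called (0.04). Cytokine genes were higher in 22 of 25 members (median 4.52, or 4.45 at the bounds; adjusted p = 2.73e-21). Il27, an interleukin 12 family gene, rose at least 69.9-fold, and Il12b by 4.52 (SE 0.055). Tnf rose by 5.53 (SE 0.1) and Ccl5 by 3.47 (SE 0.056), while Il12a (-1.86), Il18 (-1.59) and Ccl9 (-1.34) were lower. NF-kappaB targets were higher in 28 of 30 members (median 1.78, adjusted p = 1.54e-28), with Ptgs2 at 4.40 (SE 0.2), Tnip3, an inhibitor gene of NF-kappaB, at 4.11 (SE 0.06), Nfkbid lower (-0.38) and Sod2 not called. Maturation genes were higher in 21 of 22 members (median 2.68, adjusted p = 1.07e-23), with Cd40 at 4.03 (SE 0.052), Ccr7 at 2.97 (SE 0.037), Cd80 at 2.78 (SE 0.064), Cd86 at 2.37 (SE 0.056) and Cd48 lower (-0.16). Checkpoint genes were higher in 12 of 18 and lower in 6 (median 2.51, adjusted p = 0.00163), with Cd274 at 4.35 (SE 0.05) from 18.8 to 384 CPM. Socs3 rose by 4.39 (SE 0.07). All these counts were the same when adjusted over the list alone.

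Death ligand genes were higher in 7 of 13 members at 16 h and lower in 5 (median 0.49, adjusted p = 0.126), the same when adjusted over the list alone. Tnfsf10 rose from 1.98 ± 0.782 to 8.51 ± 0.825 CPM, by 2.09 (SE 0.18, adjusted p = 1.91e-17), and Nos2 had 197 counts against 1, a ratio of 168 (exact 95% interval 29.8 to 6670). Klrd1, the gene of the receptor subunit CD94, fell (-5.10, SE 0.076), and Tnfsf14 (-2.3), Klrk1 (-0.89), Ctsw (-0.87) and Ltb (-0.63) were lower. Gzmb had 9 counts against 0, or 2.56 times the floor when scaled for depth (edgeR adjusted p = 0.00774 with no filter). Prf1 had 7 against 0, or 1.99 times the floor (edgeR adjusted p = 0.0312 with no filter).

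pDC identity genes were lower in 17 of 23 members at 16 h (median -0.67, adjusted p = 2.18e-09). Siglech fell from 1640 ± 13.4 to 169 ± 1.83 CPM (-3.28, SE 0.034, adjusted p = 4.77e-78) and Tcf4 from 1610 to 732 CPM (-1.14, SE 0.035, adjusted p = 7.84e-44). Upb1 fell (-4.74, SE 0.11), Ly6d (1.98) and Tlr9 (0.54) were higher, and Klk1, Bst2, Blnk and Tlr7 were not called. Adjusted over the list alone, 3 were higher and 17 lower. Tlr7, at 0.09 (adjusted p = 0.13), was called with no expression filter (0.09) and in a fit of only the groups compared (0.08). cDC1 markers were lower in 11 of 13 members (median -2.51, adjusted p = 3.72e-05), with Naaa at -5.53 (SE 0.095), Cd36 higher at 5.49 (SE 0.054) and Batf3 not called. Monocyte and macrophage markers were lower in 6 of 13 members and higher in 3 (median -0.1, adjusted p = 0.000155). Ccr2, the monocyte chemokine receptor gene, fell (-5.92, SE 0.047), as did Csf1r, the receptor gene for macrophage colony-stimulating factor (-4.35, SE 0.072), while Fcgr1 rose by 3.41 (SE 0.28) and C1qb and Cd14 were higher.

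Cell cycle genes were higher in 31 of 34 members at 16 h (median 1.60, adjusted p = 4.99e-15), with Cenpf lower (-0.33). Cdc6, a replication licensing gene, rose by 3.40 (SE 0.12), Mcm3, a replicative helicase gene, by 3.19 (SE 0.058) and Ccne1, the cyclin E1 gene, by 3.21 (SE 0.2). MHC class I genes were higher in all 23 members (median 1.63, adjusted p = 7.07e-29), with Nlrc5 at 2.37 (SE 0.036). Apoptosis regulators were higher in 21 of 29 and lower in 6 (median 0.57, adjusted p = 0.00331), with Bik, a pro-death gene, at least 14.2-fold and Bcl2l1 at 3.66 (SE 0.068). Unfolded protein response genes were higher in 19 of 22 (median 1.23, adjusted p = 1.63e-06; adjusted p = 0.12 with an estimated correlation), with Trib3, a stress kinase-like gene, at 3.78 (SE 0.42). Glycolysis genes were higher in 13 of 22 and lower in 5 (median 0.70, adjusted p = 0.00845; adjusted p = 0.22 with an estimated correlation), with Tpi1, a triose phosphate isomerase gene, at 1.81 (SE 0.068). Immediate-early genes were higher in 12 of 24 and lower in 8 (median 0.36, adjusted p = 0.00925; adjusted p = 0.296 with an estimated correlation), with Myc at 5.05 (SE 0.084) and Klf4 lower at -4.20 (SE 0.1). These counts were the same when adjusted over the list alone. Of 14 lists called, 11 held with an estimated correlation.

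Lists not called at 16 h had adjusted p of 0.155 for cholesterol synthesis, 0.421 for MHC class II, 0.446 for p53 targets, 0.672 for cDC2 markers, T and NK cell markers and mitochondrial mRNAs, 0.796 for the Toll-like receptor pathway, and 0.947 for B cell and for neutrophil and mast cell markers. Cholesterol genes were higher in 12 of 20 members and lower in 4, or 13 and 4 adjusted over the list alone. MHC class II genes were higher in 8 of 14 and lower in 5, p53 targets higher in 14 of 20 and lower in 6, Toll-like receptor pathway genes higher in 12 of 27 and lower in 10, and B cell markers higher in 3 of 11 and lower in 8, with Pax5, a B cell transcription factor gene, at 2.64 (SE 0.06). cDC2 markers were higher in 4 of 11 and lower in 5, and T and NK cell markers higher in 4 of 6 with Txk lower. Of 4 neutrophil and mast cell markers Csf3r was higher and Prtn3 lower. The mitochondrial mRNAs mt-Nd4 (-0.83), mt-Cytb, mt-Nd5 and mt-Co1 were lower, or 3 of them adjusted over the list alone, and mt-Co1 was not called without any 1 of the 6 libraries (-0.29 to -0.35) or with no filter (-0.31). cDC2 markers had a median of 0.06, a mean of -1.37 and a test that pointed down, and Ermap was not called. The counts of the other lists not called were the same when adjusted over the list alone.

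The overlap of both times was counted. Of genes higher at 6 h, 4184 were also higher at 16 h, where 2191 would be expected if the calls were independent, and 4206 were lower at both (2226 expected). Opposite calls were found for 1164 genes (4419 expected), of which 523 were higher at 6 h and lower at 16 h. Changes of at least 2-fold in opposite directions were seen for 46 genes. The correlation across genes was 0.824, and genes are not independent replicates. No library was used for both times.

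The next comparison asked whether the effect of imiquimod differed between 16 h and 6 h. It did for 8468 genes, 4246 higher and 4222 lower at 16 h relative to 6 h. Scaled by library totals, 6951 were higher and 2257 lower (75.5% higher in place of 50.1%, a median shift of 0.33). Kntc1, a mitotic checkpoint gene, was higher by 2.65 (SE 0.12, edgeR adjusted p = 7.45e-31), Exo1, a DNA repair exonuclease gene, by 2.80 (SE 0.2), Cd81, a tetraspanin gene, by 2.86 (SE 0.18) and Serpinf1, a secreted serpin gene, by 3 (SE 0.22). Ighg2c was higher by 2.66 (SE 0.96, adjusted p = 0.0141), and by 2.00 and not called without vehicle 6 h replicate 1. Lars2, a mitochondrial tRNA synthetase gene, was higher by 2.66 (SE 1, adjusted p = 0.0436) and lost its call without any 1 of 7 libraries: vehicle 6 h replicate 1 (1.85), imiquimod 6 h replicates 1 to 3 (2.68, 2.95 and 2.40), vehicle 16 h replicates 1 and 2 (2.38 and 2.59) and imiquimod 16 h replicate 2 (1.77). It was also not called with no filter (2.70) or in a fit of only the groups compared (2.68). Gbp2, an interferon-induced GTPase gene, was lower by 4.40 (log2 -4.40, SE 0.12, adjusted p = 1.99e-47). The heat shock genes Hspa1a (-4.73, SE 0.32) and Hspa1b (-4.61, SE 0.2), whose sharing of reads was not tested, were lower. So were the glutamate receptor gene Grin2c (-4.94, SE 0.24) and the receptor gene Notch3 (-4.67, SE 0.33). Cd209a was also lower (-5.62, SE 1.1), a value that rests on 0 counts in imiquimod at 16 h.

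Of the panel, 16 genes with a called difference had a smaller or more negative effect at 16 h. The differences were largest for Il12b (-4.06, SE 0.13), Ccl5 (-2.71, SE 0.13) and Tnfsf10 (-2.57, SE 0.32, edgeR adjusted p = 7.58e-11). They were -1.82 for Ccr7, -1.67 for Irf7, -1.46 for Cd40, -1.44 for Tcf4, -1.33 for Siglech, -1.14 for Cd86, -1.09 for Tlr7, -0.82 for Bst2, -0.81 for Cd274 and -0.74 for Cd80. Il6 differed by -1.72 (SE 0.56, adjusted p = 0.00745), and by -1.16 and not called without vehicle 6 h replicate 1. Isg15 differed by -0.88 (adjusted p = 0.0144), and by -0.47 and not called without vehicle 16 h replicate 2. Tnf differed by -0.73 (adjusted p = 0.0034), and by -0.38 and not called without vehicle 16 h replicate 3. Under scaling by library totals Isg15 (-0.54) and Tnf (-0.4) were not called. Cxcl10 (-1.76, adjusted p = 0.14) was not called.

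Cell cycle genes had a higher effect at 16 h in all 34 members (median 1.66, adjusted p = 1.58e-35), with Rrm2, a ribonucleotide reductase gene, at 2.65 (SE 0.1), Mcm5, a helicase gene, at 2.41 (SE 0.087) and Tk1, the thymidine kinase gene, at 2.30 (SE 0.16). Cholesterol synthesis genes had a lower effect in all 20 members (median -1.53, adjusted p = 2.25e-43), with Hmgcs1 at -1.90 (SE 0.047), Fdps, the farnesyl diphosphate synthase gene, at -1.83 (SE 0.12) and Msmo1, a sterol oxidase gene, at -1.81 (SE 0.053). Interferon-stimulated genes were lower in 56 of 61 members (58 adjusted over the list alone; median -1.24, adjusted p = 5.84e-24), with Gbp5, an interferon-induced GTPase gene, at -3.10 (SE 0.12). Cytokine genes were lower in 16 of 25 (median -1.67, adjusted p = 8.61e-05), NF-kappaB targets in 27 of 30 (median -1, adjusted p = 3.32e-22), with Cd83 at -1.71 (SE 0.061), and maturation genes in 15 of 22 (median -1.10, adjusted p = 7.74e-13), with Icosl, a co-stimulatory ligand gene, at -2.24 (SE 0.052). pDC identity genes were lower in 19 of 23 (median -0.98, adjusted p = 3.45e-13), with Blnk, a signalling adaptor gene, at -1.52 (SE 0.054) and Ly6d and Ptprcap higher. Monocyte markers were lower in 9 of 13 (median -0.95, adjusted p = 0.00232), with Fn1, the fibronectin gene, at -3.23 (SE 0.3).

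Checkpoint genes had a lower effect at 16 h in 11 of 18 members (median -0.96, adjusted p = 0.0179), with Havcr2, the TIM-3 gene, at -1.79 (SE 0.094) and Vsir higher. Toll-like receptor pathway genes were lower in 15 of 27 and higher in 5 (median -0.40, adjusted p = 0.000743). Immediate-early genes were lower in 19 of 24, with Myc higher, or 19 lower and 2 higher adjusted over the list alone (median -0.89, adjusted p = 4.98e-06; adjusted p = 0.0635 with an estimated correlation). MHC class II genes were lower in 10 of 14 (median -0.32, adjusted p = 0.00445; adjusted p = 0.351 with an estimated correlation), with 10 lower and 1 higher adjusted over the list alone and Ciita at -1.68 (SE 0.046). Unfolded protein response genes were lower in 14 of 22, with Pdia4 and Sdf2l1 higher (median -0.39, adjusted p = 0.00618; adjusted p = 0.395 with an estimated correlation), among them Edem1, a protein degradation gene (-1.11, SE 0.048). Both of those lists had an adjusted p of 0.0834 under scaling by library totals. Death ligand genes were lower in 6 of 13 and higher in 3 (median -0.73, adjusted p = 0.0244; adjusted p = 0.102 with an estimated correlation), with Klrd1 at -2.73 (SE 0.11). The other lists called held with an estimated correlation, 10 of 14. Counts adjusted over the list alone differed for no other list.

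The lists not called in this comparison had adjusted p of 0.224 for cDC2 markers, 0.337 for apoptosis regulators, 0.4 for glycolysis, 0.456 for p53 targets, B cell markers and mitochondrial mRNAs, 0.511 for MHC class I, 0.602 for T and NK cell markers, 0.609 for cDC1 markers and 0.91 for neutrophil and mast cell markers. MHC class I genes were higher in 7 of 23 and lower in 11, apoptosis regulators higher in 10 of 29 and lower in 12, p53 targets higher in 9 of 20 and lower in 6, and glycolysis genes higher in 10 of 22 and lower in 7. cDC1 markers were higher in 4 of 13, with Cd36 at 2.10 (SE 0.11), and lower in 7. The cDC2 markers were higher in 2 of 11 and lower in 5, B cell markers higher in 4 of 11 and lower in 3, T and NK cell markers higher in 2 of 6 with Txk lower, and mitochondrial mRNAs lower in 4 of 7. Csf3r was higher and Prtn3 lower. Prtn3 was not called without imiquimod 16 h replicate 1 (-1.17) or 2 (-1.19), nor Txk without imiquimod 6 h replicate 3 (-1.04). mt-Nd4 (-0.92) was not called without any 1 of vehicle 6 h replicate 3, imiquimod 6 h replicates 2 and 3, vehicle 16 h replicates 1 and 3 and imiquimod 16 h replicates 1 and 3 (-0.85 to -0.95), with no filter (-0.89) or in a fit of only the groups compared (-0.91). Under scaling by library totals Prtn3 (-0.96), Txk (-0.86), mt-Nd4 (-0.59), mt-Nd5 (-0.57), mt-Cytb (-0.42) and mt-Co1 (-0.37) were not called. The median, mean and test differed in sign for neutrophil markers (-0.86, -0.31, up) and B cell markers (0.08, -0.02, up).

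**Figure D3:**
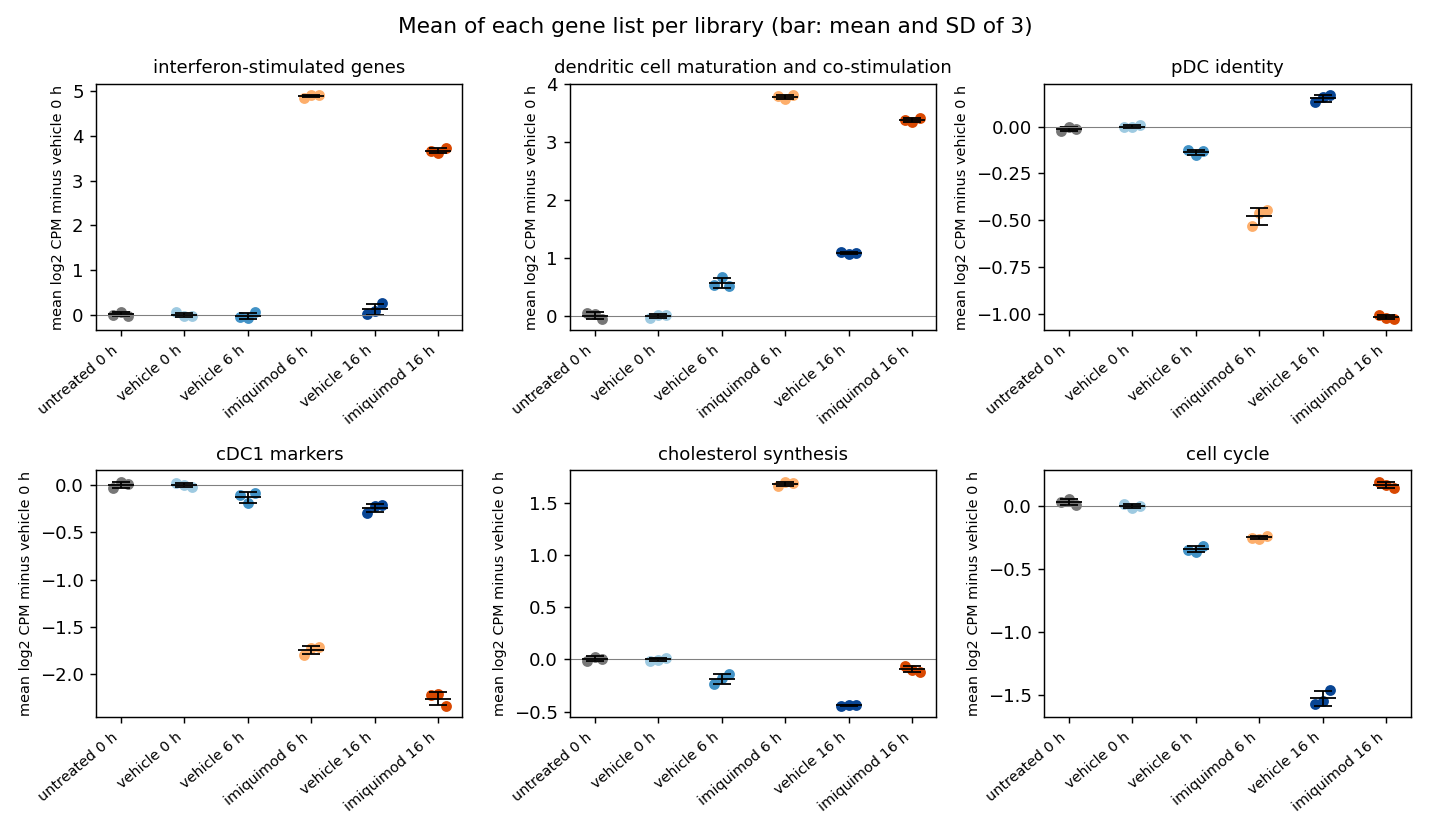
Mean log2 CPM of the members of 6 gene lists in each library, as the difference from the mean of the vehicle at 0 h; points are the 3 libraries of a group and bars the mean and SD. Cell cycle genes stood at -1.53 in the vehicle and 0.17 in imiquimod at 16 h, and cholesterol synthesis genes at 1.69 in imiquimod at 6 h and -0.09 at 16 h.

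The vehicle was compared with untreated cells at 0 h. Both were collected at 0 h, so a response to the vehicle that takes time could not be seen here. edgeR called 0 genes higher and 0 lower, with 708 of 14876 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0506, and DESeq2 called 0. Some other choices made calls, here named after their values were seen. Mmp12, a macrophage elastase gene, was called at 0.86 with DESeq2 size factors (adjusted p = 0.0423), 0.85 with no filter, 0.86 in a fit of only the groups compared, 0.96 without untreated replicate 3 and 1.06 without vehicle 0 h replicate 2. Cyp1b1, a cytochrome P450 gene, was called with no filter (1.60), without untreated replicate 3 (1.98) and without vehicle 0 h replicate 2 (1.81). Col1a2, a collagen gene (1.09), and the nuclear RNA gene Malat1 (0.16) were called with no filter and in a fit of only the groups compared (1.10 and 0.17). The fits without untreated replicate 3 and vehicle 0 h replicates 2 and 3 made 7, 2 and 1 calls. MHC class II presentation was the 1 list called, with a median of -0.05, 0 of 14 members called and a test that pointed down (adjusted p = 0.0152; adjusted p = 0.953 with an estimated correlation). The adjusted p was 0.166 under scaling by library totals. The other 23 lists had adjusted p from 0.217 to 0.997 and medians from -0.05 to 0.11. Adjusted over the list alone, 1 monocyte marker was higher and no other member was called.

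The vehicle at 6 h was compared with the vehicle at 0 h, the change with time in culture and exposure to the vehicle, without imiquimod. No untreated cells were collected at 6 or 16 h, so time and vehicle cannot be told apart at either time. Fosb, an immediate-early transcription factor gene, fell from 164 to 1.28 CPM (-6.98, SE 0.1, edgeR adjusted p = 1.33e-55), and Cd69, an early activation marker gene, from 90.7 to 8.2 CPM (-3.47, SE 0.07). Nr4a2, a nuclear receptor gene (-3.92, SE 0.15), Atf3, a stress transcription factor gene (-3.42, SE 0.12), and Per2, a circadian clock gene (-3.06, SE 0.13), fell. Ccl22, a chemokine gene of mature dendritic cells, rose from 4.97 to 67.5 CPM, by 3.76 (SE 0.1, adjusted p = 1.91e-27). Apol7c, an apolipoprotein L gene, rose by 3.61 (SE 0.082), Mreg, a melanosome transport gene, by 2.77 (SE 0.093), H2-Eb2, a class II beta chain gene, by 2.10 (SE 0.12) and Il4i1, an amino acid oxidase gene, by 2.00 (SE 0.058). There were 3868 genes higher and 4003 lower. The libraries of the vehicle at 6 h also held a larger and more variable share of rRNA-like counts, 9.301% (SD 1.42), than those of imiquimod at 6 h, 6.197% (SD 0.125), or the vehicle at 0 h, 5.252% (SD 0.348).

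Immediate-early genes were lower in 18 of 24 members at 6 h of vehicle and higher in 5 (median -1, adjusted p = 2.25e-32), with Fos at -3.01. Unfolded protein response genes were lower in 19 of 22, or 20 adjusted over the list alone (median -0.48, adjusted p = 3.58e-11). Maturation genes were higher in 11 of 22 and lower in 5 (median 0.37, adjusted p = 2.34e-05), with Socs2, a cytokine signalling inhibitor gene, at 3.31. Cell cycle genes were lower in 17 of 34 and higher in 11 (median -0.05, adjusted p = 9.66e-05), with Ccne2 at -1.67. cDC2 markers were lower in 7 of 11, with Tmem176a and Tmem176b higher (median -0.67, adjusted p = 3e-04), and Mgl2 at -2.49. Death ligand genes were lower in 5 of 13, with Ltb and Gzmm higher (median -0.31, adjusted p = 0.00283). Gzmm was not called without any 1 of vehicle 0 h replicates 1 to 3 or vehicle 6 h replicates 1 and 2 (0.55 to 0.81). Glycolysis genes were lower in 12 of 22 and higher in 4, or 13 and 4 adjusted over the list alone (median -0.23, adjusted p = 0.0127; adjusted p = 0.329 with an estimated correlation). Cholesterol genes were lower in 11 of 20 and higher in 3 (median -0.15, adjusted p = 0.0074; adjusted p = 0.329 with an estimated correlation), with Insig1 at -0.77. The other 6 of 8 lists called held, and their counts, where no other is given, were the same when adjusted over the list alone.

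The other lists were not called in this comparison. Interferon-stimulated genes were higher in 16 of 61 and lower in 15 (adjusted p = 0.351), cytokines higher in 6 of 25 and lower in 11 (0.621), with Ccl4, a chemokine gene, at -4.67, and NF-kappaB targets higher in 13 of 30 and lower in 15 (0.493). pDC identity genes were higher in 6 of 23 and lower in 11 (0.116), cDC1 markers higher in 3 of 13 and lower in 9 (0.277), monocyte markers lower in 10 of 13 with Ms4a7 higher (0.102) and checkpoint genes lower in 7 of 18 with Arg2 and Socs1 higher (0.102). MHC class II genes were lower in 9 of 14 (0.353), class I genes higher in 7 of 23 and lower in 8 (0.719), Toll-like receptor pathway genes higher in 8 of 27 and lower in 13 (0.493), apoptosis regulators higher in 10 of 29 and lower in 8 (0.621) and p53 targets higher in 7 of 20 and lower in 5 (0.493). Adjusted p was 0.664 for mitochondrial mRNAs, 0.693 for B cell, 0.731 for neutrophil and 0.971 for T and NK cell markers. Adjusted over the list alone, lower calls were 14 for the Toll-like receptor pathway and 6 for p53 targets, B cell markers had 3 higher and 5 lower, and mitochondrial mRNAs 1 lower. The median, mean and test differed in sign for interferon-stimulated genes (0, -0.02, up), NF-kappaB targets (-0.11, 0.14, up), MHC class I (0.02, -0.03, down), T and NK cell markers (0.09, -0.29, up) and apoptosis regulators (0.1, 0.09, down).

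The vehicle at 16 h was compared with the vehicle at 0 h in the same way. Apol7c rose from 5.78 to 296 ± 26.1 CPM, by 5.68 (SE 0.067, edgeR adjusted p = 1.73e-63), and Fscn1, an actin-bundling gene of mature dendritic cells, by 4.63 (SE 0.069, adjusted p = 1.03e-58). Socs2 rose by 4.51 (SE 0.15), Slco5a1, a transporter gene, by 4.42 (SE 0.13) and Synpo2, an actin-binding gene, by 4.39 (SE 0.14). Fosb fell (-7.51, SE 0.11, adjusted p = 1.94e-55), as did Cd69 (-3.98, SE 0.078), Fos (-3.79, SE 0.15), Lmna, the lamin A gene (-3.63, SE 0.16), and Alox5, the leukotriene-forming lipoxygenase gene (-3.56, SE 0.16). There were 4222 genes higher and 4469 lower, and 3680 and 5035 under scaling by library totals. The share of mitochondrial rRNA counts was 9.555% (SD 0.269) in the vehicle at 16 h, 5.461% (SD 0.443) in imiquimod at 16 h and 5.862% (SD 0.16) in the vehicle at 0 h.

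Cell cycle genes were lower in all 34 members at 16 h of vehicle (median -1.56, adjusted p = 2.64e-53), with Cdc6 at -2.56 (SE 0.13) and Rrm2 at -2.37 (SE 0.078). Against the vehicle at 0 h, a list comparison added after the data were seen, cell cycle genes in imiquimod at 16 h had a median of 0.07 (adjusted p = 0.343), with 17 of 34 higher and 13 lower. Maturation genes were higher in 14 of 22 (median 0.76, adjusted p = 7.87e-16) and immediate-early genes lower in 18 of 24 (median -1.13, adjusted p = 3.01e-23). These lists, 3 of 11 called, held with an estimated correlation. The others were unfolded protein response genes, lower in 19 of 22 (median -0.48, adjusted p = 2.24e-07; adjusted p = 0.142 with an estimated correlation), and cholesterol genes, lower in 17 of 20 (median -0.40, adjusted p = 2e-07; adjusted p = 0.0825 with an estimated correlation). cDC2 markers were lower in 7 of 11 (median -0.71, adjusted p = 0.00349; adjusted p = 0.0825 with an estimated correlation), glycolysis genes in 13 of 22 (median -0.53, adjusted p = 0.00406; adjusted p = 0.219 with an estimated correlation) and death ligand genes in 5 of 13 (median -0.35, adjusted p = 0.0086; adjusted p = 0.0825 with an estimated correlation), with Tnf at -2.01. Interferon-stimulated genes were higher in 20 of 61 and lower in 12 (median 0.12, adjusted p = 0.0086; adjusted p = 0.607 with an estimated correlation), with Gbp2 at 3.01 (SE 0.12). NF-kappaB targets were higher in 14 of 30 and lower in 10 (median 0.08, adjusted p = 0.0086; adjusted p = 0.219 with an estimated correlation), or 15 and 10 adjusted over the list alone, with Traf1 at 2.19. pDC identity genes were higher in 10 of 23 and lower in 5 (median 0.12, adjusted p = 0.0142; adjusted p = 0.219 with an estimated correlation), with Siglech at 0.56. Counts for the other lists called were the same when adjusted over the list alone.

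Lists not called in the vehicle at 16 h included cytokines, higher in 8 of 25 and lower in 8 (adjusted p = 0.272), with Ccl5 at 3.72, Il12b at 3.60 and Ccl4 at -4.77. Checkpoint genes were higher in 5 of 18 and lower in 8 (0.756), with Arg2, an arginase gene, at 5.50. cDC1 markers were higher in 4 of 13 and lower in 8 (0.0921), with Xcr1, a chemokine receptor gene, at -1.93. MHC class II genes were higher in 3 of 14 and lower in 10 (0.461), class I genes higher in 11 of 23 and lower in 5 (0.531), and Toll-like receptor pathway genes higher in 10 of 27 and lower in 7 (0.993). Monocyte markers were lower in 7 of 13 (0.385), apoptosis regulators higher in 10 of 29 and lower in 9 (0.523) and p53 targets higher in 8 of 20 and lower in 4 (0.523), or 9 and 4 adjusted over the list alone. Adjusted p was 0.698 for mitochondrial mRNAs, 0.756 for neutrophil, 0.83 for B cell and 0.903 for T and NK cell markers, and 2 B cell markers were higher and 1 lower adjusted over the list alone. The median, mean and test differed in sign for cytokines (-0.19, -0.24, up), checkpoint genes (0.04, 0.35, down), the Toll-like receptor pathway (0.05, -0.02, down), apoptosis regulators (0.03, -0.11, down), B cell markers (-0.01, 0.03, up) and T and NK cell markers (0.14, -0.11, up).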

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

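The splits of the libraries and the test of shared read windows were set before their results were seen, and the tests on the share of pDCs and on other cell types were chosen after. The results below were picked out because the effect of imiquimod differed between 6 h and 16 h. Of the genes tested, 4246 had a higher and 4222 a lower effect at 16 h.

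The listed cell cycle genes had a higher effect at 16 h (median 1.66). Kntc1 at 2.65 and Exo1 at 2.8, which are not members of that list, also had a higher effect. The list stood at -1.53 in the vehicle and 0.17 in imiquimod at 16 h, as differences in mean log2 CPM from the vehicle at 0 h, so that most of the difference lay in the vehicle. More cells of another listed type could give such a rise, and 0 of 6 lists of other cell types were called higher at 16 h, which cannot tell, since markers already present could hide a small share. Under scaling by library totals 6951 genes had a higher and 2257 a lower effect, so the split of directions depends on the scaling.

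pDC identity genes had a lower effect at 16 h (median -0.98), with Siglech at -1.33, Tcf4 at -1.44, Tlr7 at -1.09 and Bst2 at -0.82. As differences in mean log2 CPM from the vehicle at 0 h, the list went from -0.48 to -1.02 with imiquimod. With vehicle it went from -0.14 to 0.15, so the larger part lay in imiquimod and the rest in the vehicle. From 6 h to 16 h of vehicle, Siglech rose from 43871 to 55038 raw counts and Tlr7 from 6861 to 9167. A smaller share of pDCs among the cells would raise the markers of the other cells. For imiquimod against vehicle at 16 h the median of the cDC1 markers was -2.51 (SE 0.81, 13 genes). The SE of a list here is the SD of its members over the square root of their number. It belongs to a mean and not to the median shown, and it treats genes as independent, which they are not. Medians there were 0.06 (SE 1.09) for cDC2, -0.1 (SE 0.7) for monocyte and -0.41 (SE 0.55) for B cell markers. T and NK cell markers had a median of 1.67, with 4 of 6 higher and 1 lower (camera adjusted p = 0.672, fry adjusted p = 4.19e-07). Neutrophil and mast cell markers had a median of -0.38. The cDC1, cDC2, monocyte and B cell markers thus did not rise as a group at 16 h, but whether imiquimod itself lowers them was not tested. For the difference between the times cDC1 markers were not called (camera adjusted p = 0.609). A changed share is left open. Monocyte and macrophage markers also had a lower effect at 16 h (median -0.95).

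Interferon-stimulated genes had a lower effect at 16 h (median -1.24), with Isg15 at -0.88, Irf7 at -1.67 and Gbp2 at -4.4. As differences in mean log2 CPM from the vehicle at 0 h, the list went from 4.89 to 3.67 with imiquimod. With vehicle it went from -0.02 to 0.12, so for the list the larger part lay in imiquimod. Gbp2 rose by 3.01 from 0 to 16 h of vehicle, and no listed gene rose by more than 1.45 by 6 h. Part of its value thus lay in the vehicle. Counts of type I and III interferon mRNA with imiquimod were low (49 at 6 h and 18 at 16 h). Ifng, a type II interferon gene, had 43 counts at 6 h and 195 at 16 h. Loss of reads shared between genes was tested for type I: a median of 12.9% of the 75 nt windows of 13 Ifna genes (0 to 37.3%) and 0% of those of Ifnb1 were shared with another gene's transcripts. Loss of reads shared with other annotated transcripts is therefore excluded as the whole cause of the low type I counts. The strand setting, copies outside the annotation, production between the times sampled and production by few cells were not tested.

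The other values are given without weighing. Cytokine genes had a median of -1.67, with Il12b at -4.06, Ccl5 at -2.71, Il6 at -1.72 and Tnf at -0.73. From 6 h to 16 h Il6 went from 153 to 256 CPM with imiquimod and from 0.133 to 0.772 CPM with vehicle, Ccl5 from 240 to 223 and from 3.33 to 20.2 CPM, and Il12b from 900 to 313 and from 2.33 to 13.6 CPM, so the larger part of their lower log2 effects lay in the vehicle. Tnf went from 294 to 105 CPM with imiquimod and from 3.82 to 2.24 CPM with vehicle. Death ligand genes had a median of -0.73, with Tnfsf10 at -2.57, and the list was not called with an estimated correlation (adjusted p = 0.102). Maturation genes had a median of -1.1, with Ccr7 at -1.82, Cd40 at -1.46, Cd86 at -1.14 and Cd80 at -0.74. As differences in mean log2 CPM from the vehicle at 0 h, the list went from 3.78 to 3.38 with imiquimod and from 0.57 to 1.09 with vehicle, and Ccr7 went from 1350 to 1140 CPM and from 48.7 to 146 CPM, so for the list and Ccr7 the larger part lay in the vehicle. Cd40 went from 676 to 270 CPM with imiquimod and from 15.1 to 16.6 CPM with vehicle. Checkpoint genes had a median of -0.96, with Cd274 at -0.81, of which the larger part lay in the vehicle. Medians were -1.53 for cholesterol synthesis, -1 for NF-kappaB targets, -0.89 for immediate-early genes, -0.4 for the Toll-like receptor pathway, -0.39 for the unfolded protein response and -0.32 for MHC class II. With an estimated correlation the immediate-early (adjusted p = 0.0635), unfolded protein (0.395) and MHC class II (0.351) lists were not called. Among single genes, Serpinf1 stood at 3, Cd81 at 2.86, Ighg2c at 2.66, Lars2 at 2.66, Cd209a at -5.62, Grin2c at -4.94, Hspa1a at -4.73, Notch3 at -4.67 and Hspa1b at -4.61.

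Whether other divisions of the same libraries give as many calls was tested for each comparison. For the difference between the effects, 2 of 100 splits (drawn from 200 distinct ones) gave as many as the real 8468, the real one among them. The other, with 12228 calls, exchanges the treatments at 1 time and so sums both effects, which points to the structure of the samples. A further 18 splits gave 2952 to 7741 calls. Splits that mix imiquimod and vehicle libraries move the treatment effect into the spread or keep it at 1 time, so they do not stand for equal effects at both times and do not settle whether chance is excluded. For the comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. Imiquimod at 6 h had 11439 calls and the highest other split 0 (1 of 10 as large), imiquimod at 16 h 11490 and 0 (1 of 10), the vehicle at 6 h 7871 and 0 (1 of 10), and the vehicle at 16 h 8691 and 0 (1 of 10). For the vehicle at 0 h the real split had 0 calls, the highest other 9, and 10 of 10 were as large.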

How the results depend on the processing

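Alternatives were set before the data were examined, with exceptions chosen after seeing the data. These were scaling by library totals, leaving out the rRNA and rRNA-like genes, and the lists against the vehicle at 0 h. Over all alternatives, values of named genes stayed on the same side of the threshold in 9403 cases, were no longer called in 136, became called in 12 and reversed in 1. Direction was compared only for genes called in the main fit, so a turn among genes not called there was not counted. The reversal was Tcf4 at 6 h, at -0.05 in place of 0.30 under library totals, a scaling that leaves out the TMM factors of imiquimod at 6 h (0.8174 to 0.8374).

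Counts of calls for imiquimod stayed within 1.5 times the main count, except under library totals: 3704 higher at 6 h in place of 5602, and 6951 higher and 2257 lower for the difference between the effects in place of 4246 and 4222. With each library left out, the counts ran from 5428 to 5527 higher and 5598 to 5729 lower at 6 h, 5628 to 5682 and 5416 to 5486 at 16 h, and 4040 to 4223 and 4029 to 4255 for the difference. DESeq2 gave 5538 and 5393, 5538 and 5374, and 3637 and 4096.

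For the vehicle at 0 h, 0 higher became 1 with DESeq2 size factors, 4 with no filter, 4 in a fit of only the groups compared, 1 under library totals and 0 to 4 with a library left out. Lower calls became 1 with no filter, 1 with only the groups compared and 0 to 3 with a library left out. The cause was not tested.

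Of 24 lists, camera called 14, 14, 14, 1, 8 and 11 for imiquimod at 6 h, at 16 h, their difference and the vehicle at 0, 6 and 16 h. With an estimated correlation these were 13, 11, 10, 0, 6 and 3. fry, which asks whether a list moves and does not compare it with other genes, called 21, 22, 23, 0, 18 and 20. Library totals gave 0 for the vehicle at 0 h. The cause of these differences was not tested.

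With the replicate block, 5579 genes were higher and 5821 lower at 6 h of imiquimod, 5803 and 5645 at 16 h, and 4210 and 4188 for the difference. Residuals of libraries with the same number had a mean correlation of -0.0151 (0.00759 for other numbers), and 1 of 18 libraries best matched its own number. No pairing by number was thus detected, but whether libraries of the same number share a culture or animal is not known. With the block camera did not call the death ligand list for the difference (adjusted p = 0.0521) or the immediate-early list at 16 h of imiquimod (0.0827), and called glycolysis at 6 h of imiquimod (0.0401) and monocyte markers at 6 h of vehicle (0.0385). For the difference, Lars2 (2.61) and mt-Nd4 (-0.92) were not called with the block, nor was mt-Co1 at 16 h of imiquimod (-0.31).

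Depth limits genes with few counts, such as the type I and III interferon genes: with a floor of 3 counts, a gene under 0.0771 to 0.0913 CPM in a group cannot be told from absent.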

Other observations

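Genes in this part were chosen after their values were seen. Cd8a, which marks the CD8 alpha chain of some dendritic cells and T cells, rose from 7.06 to 1820 CPM with imiquimod at 6 h (8.01, SE 0.054) and from 6.95 to 910 CPM at 16 h (7.03, SE 0.056). Ccr2 fell from 1320 to 71.1 CPM at 6 h and from 1730 to 28.5 CPM at 16 h, and Cd36 rose from 12.9 to 136 and from 19.4 to 873 CPM.

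Among antibody constant region genes, Ighg2c rose by 7.17 at 6 h and 9.83 at 16 h and Ighg2b by 5.28 and 7.09, while Ighm rose by 0.40 and 0.64. Prdm1, a plasma cell factor gene, rose by 2.14 and 1.84, Pax5 by 2.56 and 2.64, and Xbp1 fell (-0.25 and -0.82). Ebf1, a B cell transcription factor gene, fell (-0.37 and -0.40), and 8 of 11 B cell markers were lower at each time.

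The mitochondrial genes mt-Co2 and mt-Co3 had 35 and 34 counts over the 18 libraries, where mt-Co1 had 674360 and mt-Cytb 86041. Of their 75 nt windows, 99.5% and 99.9% were shared with another gene's transcripts, against 39.8% for mt-Co1 and 0% for mt-Cytb. mt-Co2 and mt-Co3 were under the expression filter and entered no comparison.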
